A study of Drosophila melanogaster with 3 samples.

How the data were processed

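The series holds chromatin immunoprecipitation with sequencing (ChIP-seq) of whole *Drosophila melanogaster* prepupae of both sexes pooled. The flies carried a transgene for the protein net with green fluorescent protein (GFP) fused to its C-terminal end, and chromatin was sheared by sonication and precipitated with an antibody against GFP, per the labels' protocols. The gene net encodes a transcription factor of the basic helix-loop-helix (bHLH) class that acts in wing vein patterning. The 3 libraries are biological replicates numbered 1, 3 and 4 in the labels and form 1 group. No control library is among the samples used here, so there was no comparison between groups, and each test compared peaks with the genome, with flanking sequence, with weaker peaks or between libraries.

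The deposited files are peak lists on genome builds dm6 and dm3. Per the deposited file descriptions, each library has a relaxed list of peaks and background made as input for the irreproducible discovery rate (IDR) procedure. This procedure is meant to keep peaks that rank alike across replicates. A further relaxed list was called on the pooled alignments of the libraries, with a control alignment that was not analysed here, and an IDR-thresholded list was derived from these. The names and versions of the aligner and peak caller are not given in the sources used here. Each relaxed list holds 30000 peaks, so its length says nothing of a library's depth. The peak lists give no read counts, and the depth of each library is unknown. The dm3 IDR-thresholded list is described as derived from the pooled list and the list of replicate 4, while the dm6 list names all 3 libraries. The dm6 lists were used throughout and the dm3 lists served as an alternative.

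The signal of each peak is the authors' value, deposited per peak, and was used only to rank peaks within a list. The lists also hold the authors' −log10 q-value per peak, and 4491 of the 7571 IDR peaks share its highest value of 3.95, so peaks were not ranked by it. The summit offset deposited with each peak gave the summit position. All 7571 dm6 IDR peaks are in the pooled list with the same signal, and they are the 7571 peaks of highest signal in it. A ranking of these peaks is therefore a ranking of the pooled libraries. The IDR step in effect set the length of this list, and a place in it does not show that a peak ranked alike across libraries. Overlapping peaks with separate summits were counted separately.

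Chromosome arms and gene models came from the Release 6 genome sequence, which is build dm6, and from Ensembl release 115. Transposable elements and pseudogenes were left out, which left 17947 genes, of which 13968 code for protein, and 23358 transcription start sites (TSSs). A summit within 500 bp of a TSS was called promoter, and the others were called exon, intron or intergenic in that order. Coordinates are 1-based on dm6.

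The share of peaks per arm was compared with the arm's share of sequenced length by an exact two-sided binomial test with Benjamini-Hochberg adjustment. Replicate recovery was the share of IDR peaks with a summit within 100 bp of a summit among the 7571 highest-signal peaks of a library. Intervals on shares are exact 95% Clopper-Pearson intervals and treat peaks as independent, so they cover counting error only. Chance levels for recovery and location came from 1000 random placements of the summits within their arm, for which the smallest two-sided permutation p is 0.002. Spearman's rho between libraries was computed across peaks, which are not independent replicates, and has no p. The promoter share of the 1892 IDR peaks of highest and of lowest signal was compared by a permutation test with 100000 resamples. E-boxes, the CANNTG sequences that bHLH proteins recognise, were sought within 50 bp of the summit and in windows of the same length centred 250 bp away on both sides. Summits were compared with the right-hand flank by the exact McNemar test, over all E-boxes and for each of 10 cores. All 6-mers, each merged with its reverse complement, were compared between summits and flanks by Fisher's exact test. Neither the flanking windows of neighbouring peaks nor overlapping words are independent.

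A gene was called bound if an IDR summit lay within it or within 2 kb of it. This rule does not assign a peak to the gene it may act on, and 1 peak can make several genes bound. Nor does it separate binding of net from signal that any GFP precipitation may give. The bound share of 11 gene lists and 8 cell type marker lists was compared with 10000 random lists matched on decile of gene span, two-sided, with Benjamini-Hochberg adjustment over the 19 lists and a smallest p of 0.0002. Random lists were drawn from protein-coding genes, and from all genes for the tRNA list. They do not keep the clustering of list members that share a peak, such as neighbouring tRNA, cuticle protein or Enhancer of split genes. The p of such lists may therefore be too small. Random placements of the peaks, an alternative, leave the genes in place. They scatter each peak singly and do not keep clusters of peaks, so they can bind more genes than clustered peaks would. Their p for a list with few bound genes may therefore be too small. Of the fixed symbols, 10 were matched through a newer name in the annotation. Tests, lists and the alternatives not named here or in the closing part as added were fixed before the data were examined. Genes named are net, rho, the genes with the nearest TSS to the 25 IDR peaks of highest signal, and up to 4 bound members per list by highest signal; 1 gene that this rule selects is not reported here. The 5 6-mers and the E-box cores with the largest enrichment are also named.

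Alternatives covered the build, stricter peak sets, other match rules and windows, and the relaxed peaks as background. Each library was also left out in turn, keeping the peaks matched in both remaining libraries, whether or not the third matched. The peaks kept are those of the IDR list, with summits called on the pooled alignments of all 3 libraries. The library left out therefore still shaped which peaks could be kept and where their summits lay. Comparison with random genome windows of the same GC count, 5 per summit and drawn in proportion to the peaks of each arm, was added after seeing the data. A first set of such windows, drawn in equal numbers per arm, gave too much weight to chromosome 4 and was replaced after its result was seen; it gave the same direction for E-boxes. The tests of promoter share, gene lists, 6-mers and E-boxes and the matching of summits were run on simulated data, while the test per arm and that of strong against weak peaks were not. For the promoter share of 7571 summits, a planted share expected to read 48.7% was measured as 48.5%, and 7% of 100 random placements were called. A planted list of 25 genes with 22 bound was called, as were 2% of 200 random lists. In that simulation each gene was bound independently of its span and its neighbours. It therefore cannot show false calls that come from span or from list members sharing a peak. Of all 6-mers, 0 were called in random windows, and both planted words had the lowest p. Random windows and their flanks are alike in base composition, while IDR summits had 36.6% GC against 43.9% and 44.2% in their flanks. The simulation of 6-mers therefore cannot show calls that come from base composition. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.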

Results

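The binding of GFP-tagged net was measured by anti-GFP ChIP-seq in whole prepupae, the stage between larva and pupa, in 3 biological replicates of a transgenic fly line. The deposited data describe where the tagged protein's chromatin was enriched over a control alignment. The IDR-thresholded list on build dm6 held 7571 peaks with a median width of 460 bp, and they covered 2877 kb of the genome. Signal, the authors' own value per peak, ranged from 134 to 3742 with a median of 225. The median distance between neighbouring summits was 4720 bp, and merging overlapping peaks left 6924 regions. Of the 13968 protein-coding genes, 4804 (34.4%) had an IDR summit within the gene or 2 kb of it. The depth of the libraries is unknown, and no count of reads stands behind these values. Keeping only the IDR peaks matched in all 3 libraries left 4297 peaks, and 4914 remained with matches in both libraries other than replicate 3.

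The highest signal, 3742, was 35 bp upstream of a TSS of Ugalt (FBgn0024994), which encodes a UDP-galactose transporter, in intergenic sequence on X from 2703673 to 2704102. This peak had a mean rank of 1.33 ± 0.577 (SD, n = 3) in the separate libraries. The next, with signal 3538, lay in an intron of ush on 2L from 480557 to 481378, where the nearest TSS, 1369 bp away, was that of the transcription factor gene cbt (FBgn0043364). Its mean rank was 2.67 ± 1.53 (SD, n = 3). A peak of signal 3257 lay in the 5′ UTR of PNPase (FBgn0039846), which encodes a mitochondrial polynucleotide phosphorylase, on 3R from 31404453 to 31404856. The 5′ UTR of Chro, which encodes a chromodomain protein, held a peak of signal 2453 on 3L from 22878706 to 22879111. Upstream of the small heat shock gene Hsp27 by 138 bp, intergenic sequence on 3L from 9383684 to 9384129 held a peak of signal 2291, with a mean rank of 18.3 ± 2.52 (SD, n = 3).

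Of the 25 peaks of highest signal, 13 had a TSS within 500 bp, and 8 of the other 12 lay in introns. The genes nearest to the remaining 20 were CG14100, CG11050, CG13323, larp, CG32772, CG11362, CenG1A, CG18549, CG4496, lncRNA:CR46035, lncRNA:CR44619, lncRNA:CR31044, Lk6, CG31668, HmgZ, Tcs5, SLC5A11, mRpL41, CG12769 and Tina-1. Nearest genes were up to 11904 bp away, at CG13323. All 25 peaks were matched in each of the 3 libraries, where none ranked below 39.

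Peaks were found at net itself and at rho. The gene rho encodes a protease that activates ligands of the EGF receptor, and in the wing it promotes vein formation and is repressed by net. At net (FBgn0002931, 2L from 82421 to 87387, minus strand), summits lay 86 bp and 286 bp upstream of the TSS, in intergenic sequence at 87473 and 87673. Their signals were 486 and 298. The nearer one ranked 1084 in the IDR list and on average 1231 ± 642 (SD, n = 3) in the libraries. The farther one ranked 4794 ± 4221 (SD, n = 3), a spread between libraries almost as large as the mean. A stronger peak, of signal 633, lay farther upstream from 91885 to 92135, with its nearest TSS that of Zir. At rho (FBgn0004635, 3L from 1463811 to 1468944, plus strand), 1 summit at 1464661 lay in an intron, 850 bp downstream of a TSS, with signal 323 and a mean rank of 2371 ± 84.6 (SD, n = 3). Another, at 1463788, lay 23 bp upstream of the TSS, with signal 196 and library ranks of 4244, 2817 and 21303. The rho locus lies inside an intron of Ptp61F on the opposite strand. Because tagged net is made from a transgene, the peaks at net do not distinguish the native locus from inserted copies of the same sequence.

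**Figure D1:**
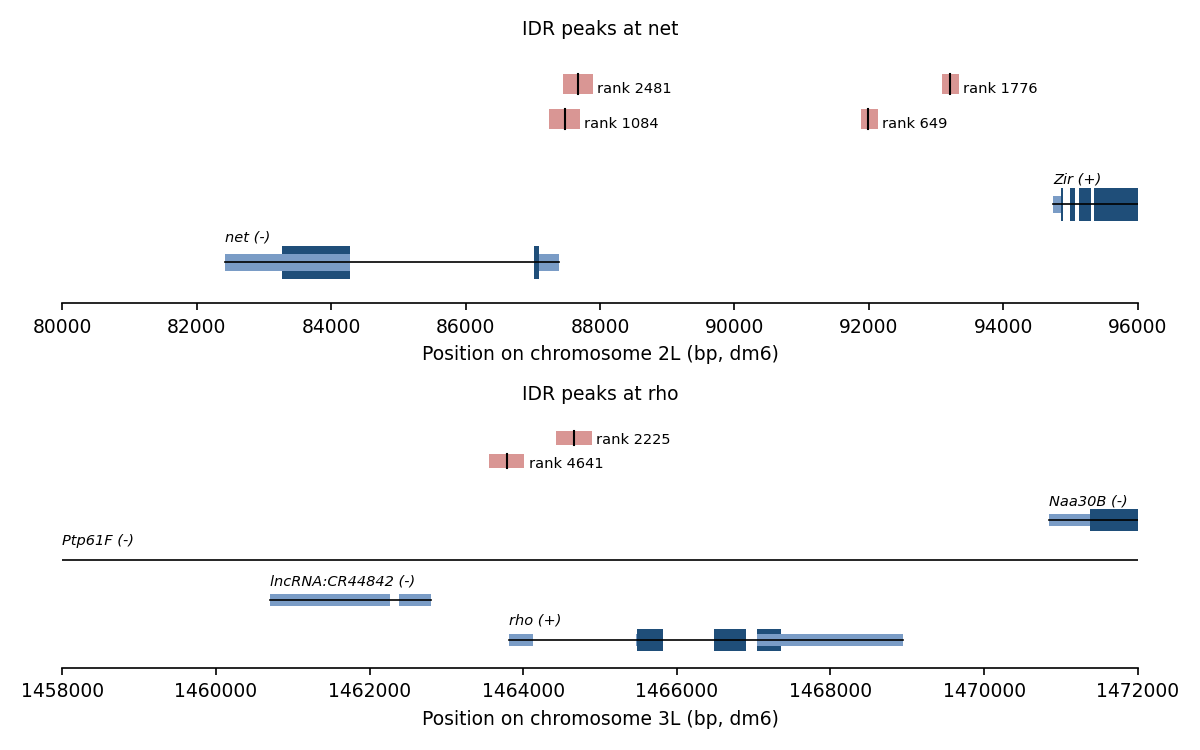
Gene models and IDR peaks at net (upper map, chromosome 2L) and rho (lower map, chromosome 3L) on dm6, with position in bp on each x axis. Dark boxes are coding sequence, lighter boxes other exons, lines introns or gene spans with the strand in brackets, and red boxes are peaks with the summit as a black tick and the rank by signal among the 7571 peaks; 2 peaks stand just upstream of net and 2 at the start of rho.

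The first comparison asked how alike the 3 libraries were. On average 79.9% ± 1.30 (SD, n = 3) of IDR peaks had a summit within 100 bp among the equally long top list of a library. The share was 78.5% (95% interval 77.6 to 79.4) in replicate 1, 81.1% (80.2 to 81.9) in replicate 3 and 80.2% (79.3 to 81.1) in replicate 4. In all 3 libraries together, 4297 of 7571 peaks (56.8%, 55.6 to 57.9) were matched, against a mean of 0.542% for random placements (permutation p = 0.002, the smallest 1000 placements can give). A further 2106 peaks were matched in 2 libraries, 1051 in 1 and 117 in 0. Recovery fell with signal, from 94.8% (93.7 to 95.7) of the 1893 strongest peaks to 5.23% (4.27 to 6.33) of the 1892 weakest. Spearman's rho of signal across peaks was 0.749 between replicates 1 and 3, 0.725 between 1 and 4 and 0.723 between 3 and 4, over 6792 to 6854 peaks matched in both. The IDR list was made from these libraries, so the recovery is not an independent check of it. Because it holds the 7571 strongest pooled peaks and was matched to equally long lists, peaks near its lower limit lose matches by construction, and the fall with signal follows in part from that.

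**Figure D2:**
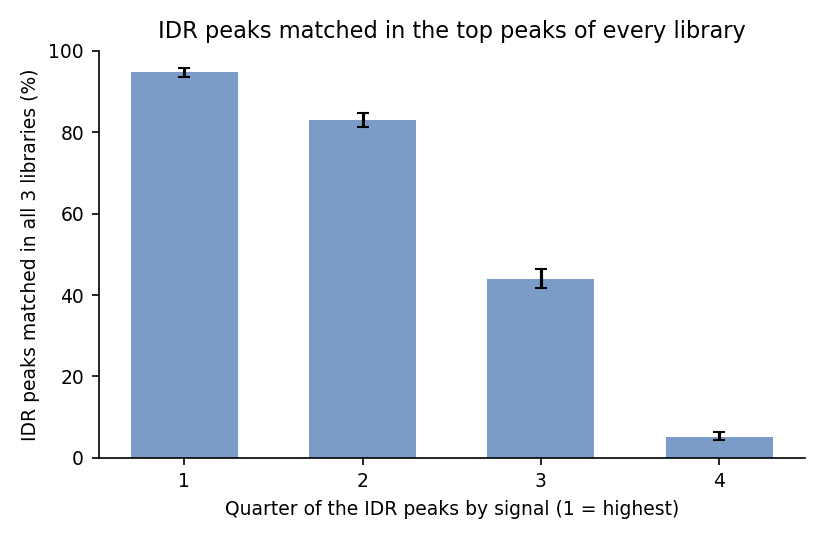
Share of IDR peaks (y axis, %) matched in the top 7571 peaks of all 3 libraries, for 4 groups of IDR peaks of equal size ordered by signal (x axis, 1 the highest). Error bars are exact 95% intervals; the share falls from 94.8% in the strongest group to 5.23% in the weakest, in part by construction, since the weakest group adjoins the limit of equally long lists.

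The distribution over chromosomes was compared with sequenced length. Chromosome 4, a small and largely heterochromatic chromosome, carried 10 peaks where its length would give 73.5, a ratio of 0.136 (exact binomial test, adjusted p = 7.7e-20). The Y chromosome carried 0 peaks, with 188 expected by length (exact binomial test, adjusted p = 2.0e-82). By the same exact test, arm 3L with 1693 peaks (ratio 1.09, adjusted p = 8.3e-05) and X with 1415 (ratio 1.09, adjusted p = 0.00063) were above their length. The 1347 peaks on 2L (ratio 1.04), 1344 on 2R (0.962) and 1762 on 3R (0.995) did not pass the test. The exact test takes peaks as independent, although some overlap or lie close together, so its p may be too small. Sequenced length includes repeats in which peaks are hard to call. When the expectation came from the relaxed pooled peaks outside the IDR list, no arm passed the exact test: the ratio was 0.817 for chromosome 4 (adjusted p = 0.80), 1.02 for X (adjusted p = 0.80) and 0.987 for 3L (adjusted p = 0.80). The Y chromosome could not be tested this way, since none of these relaxed peaks lay on it. Its test against length therefore cannot tell a lack of binding from sequence in which no peak is called.

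Where in genes the summits lay was compared with random placement. Promoters held 2767 summits (36.5%, 95% interval 35.5 to 37.6) against a mean of 13.4% for random placements, a 2.72-fold enrichment (permutation p = 0.002, the smallest possible here). Introns held 3388 summits (44.7%, 43.6 to 45.9; random 39.5%), also above chance, but the relaxed pooled peaks outside the IDR list had a higher share there (50.8%, 50.1 to 51.5; the difference was not tested). Exons outside promoters held 210 (2.77%, 2.42 to 3.17; random 19.7%) and intergenic sequence 1206 (15.9%, 15.1 to 16.8; random 27.4%), both below chance with the same p. The median summit was 1121 bp from a TSS, against 3434 bp in a random placement. The 20424 relaxed pooled peaks that overlapped no IDR peak had a promoter share of 18.8% (18.2 to 19.3), and the IDR peaks exceeded it (Fisher's exact test, p = 8.2e-201). No precipitation from flies with GFP alone was analysed here. Signal that any GFP precipitation may give at promoters is therefore not separated from binding of net.

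**Figure D3:**
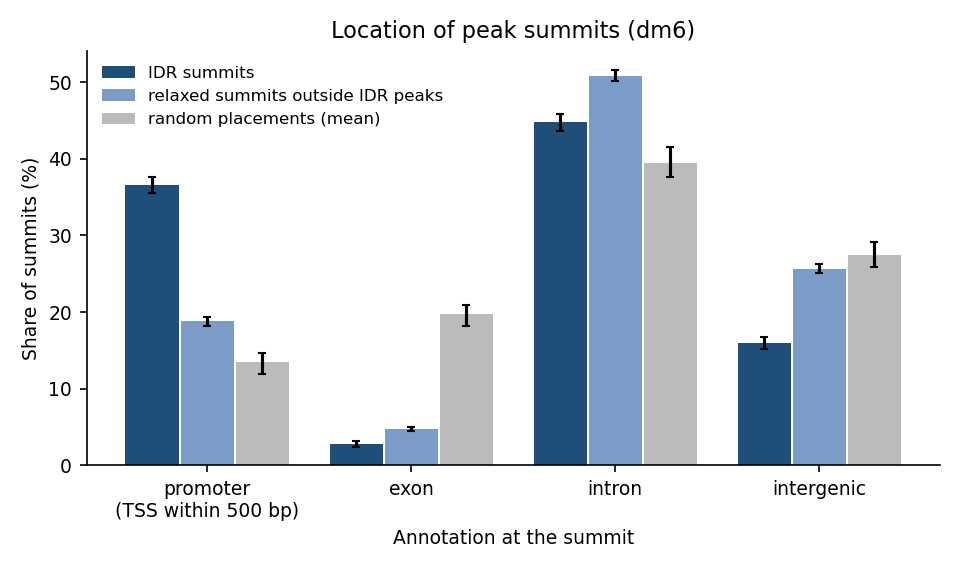
Share of summits (y axis, %) in promoters, exons, introns and intergenic sequence (x axis) for the IDR peaks, the relaxed pooled peaks outside them and random placements. Error bars are exact 95% intervals for peaks and the lowest and highest of 1000 placements for random; IDR summits reach 36.5% in promoters against a random mean of 13.4%.

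Strong peaks lay at promoters more often than weak ones. Of the 1892 peaks of highest signal, 44.9% were at promoters, against 32.0% of the 1892 of lowest signal, a difference of 12.9 percentage points (permutation test with 100000 resamples, two-sided, p = 1e-05, the smallest possible). Between them the share was 34.6% at ranks 1894 to 3786 and 34.8% at ranks 3787 to 5679, so most of the difference lay in the strongest peaks. The size of this difference depended on how peaks were chosen and ranked. With peaks ranked by their mean rank over the 3 libraries it was 4.92 points (permutation p = 0.00186), with the 3785 strongest against the 3785 weakest it was 6.34 points, and with a promoter limit of 200 bp it was 6.92 points. Among peaks matched in both remaining libraries it was 19.4 points without replicate 1, 20.2 points without replicate 3 and 9.75 points without replicate 4.

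The E-box test asked whether summits carried the sequence that bHLH proteins recognise more often than their surroundings. They did not: 36.7% of IDR summits had a CANNTG sequence within 50 bp, against 42.5% of the flanking windows, a ratio of 0.863. An E-box was at the summit alone in 1621 peaks and in the right-hand flank alone in 2039 (exact McNemar p = 5.2e-12). By core, CATATG was the only one higher at summits (3.90% against 3.08%, ratio 1.26, exact McNemar test, adjusted p = 0.00073). By the same exact test, CAACTG (ratio 0.712, adjusted p = 2.3e-07), CAAGTG (0.773, adjusted p = 0.00036), CACATG (0.756, adjusted p = 0.00042), CACCTG (0.707, adjusted p = 0.00073) and CACGTG (0.60, adjusted p = 0.0077) were lower. The other 4, CAAATG, CAATTG, CAGATG and CAGCTG, did not pass the test. Base composition also differed between the windows: GC content was 36.6% ± 10.2 (SD across 7571 windows) at summits against 43.9% and 44.2% in the flanks, and 33.4% at the 1892 strongest summits. Against random genome windows of the same GC count, a comparison added after seeing the data, the direction turned, with 36.7% of summits and 35% of windows holding an E-box (ratio 1.05, Fisher's exact test, p = 0.0048).

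**Figure D4:**
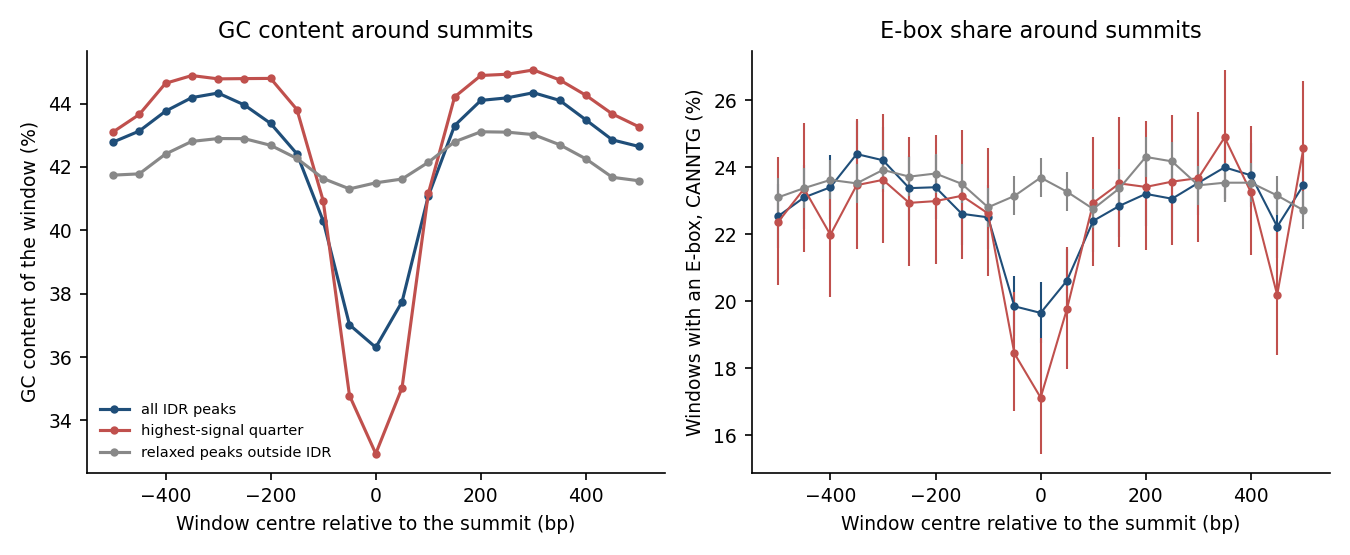
GC content (left, %) and share of 51-bp windows with an E-box (right, %, exact 95% intervals) against distance of the window's centre from the summit in bp, for all IDR peaks, the 1892 of highest signal and the relaxed pooled peaks outside the IDR list; neither y axis starts at 0. Both fall at the IDR summits, where GC content in the central window is 36.3% and the E-box share 19.7%, and the relaxed peaks show 41.5% and 23.7%.

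The open search over 6-mers gave AT-rich words at the summits. Of all words tested, 559 were higher and 995 lower at summits than in flanks (Fisher's exact test, adjusted p under the threshold of 0.05). The largest enrichments were ATATTA, at 15.7% of summits and 6.95% of flanks (ratio 2.27, Fisher's exact test, adjusted p = 2.3e-89), TACTAA (ratio 2.26), TCTTAA (2.24), ATCTTA (2.23) and TAGTAA (2.15). GC-rich words were lowest, with CGGGCC at a ratio of 0.246 (Fisher's exact test, adjusted p = 3.7e-24). Across words, the log ratio fell with the number of G and C bases (Spearman's rho = -0.873, words are not independent). Against random windows of the same GC count, 298 words were higher and 363 lower, of which 163 had passed in the opposite direction against the flanks. Of the 5 words above, ATCTTA (ratio 1.32, Fisher's exact test, adjusted p = 3.1e-08), TCTTAA (1.21, adjusted p = 3.4e-05), TACTAA (1.16, adjusted p = 0.012) and ATATTA (1.08, adjusted p = 0.029) stayed above these windows with smaller ratios, and TAGTAA (1.07, adjusted p = 0.28) did not pass.

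Genes of several signalling pathways were bound more often than genes of like span. Of 25 EGF receptor pathway genes, 22 (88.0%) were bound against 55.7% in random lists (permutation test, adjusted p = 0.0047). Raf, the kinase below Ras, had 16 summits within the gene or 2 kb, the strongest of signal 1121 in its intron on X from 2300546 to 2300892. The receptor gene Egfr had 11, the strongest of signal 830 in an intron on 2R from 21524076 to 21524451, and the ligand gene spi had 5, the strongest of signal 928 in an intron, 174 bp upstream of a TSS. The strongest peak counted for cnk, which encodes a scaffold protein of the Raf pathway, lay in the 5′ UTR of the neighbouring gene l(2)k01209, with signal 1146 and no match in replicate 4. Of 24 Notch pathway and Enhancer of split genes, 18 (75.0%) were bound against 37.1% (permutation test, adjusted p = 0.0038). Enhancer of split genes are neighbours that can share a peak, so this p may be too small. The ubiquitin ligase gene neur had its strongest peak, of signal 1327, in an intron on 3R from 9031843 to 9032205, and mam (1062) and numb (902) also had theirs in introns. The peak counted for E(spl)m8-HLH (1120) lay in an intron of the neighbouring gene gro. Of 20 BMP pathway genes, 16 (80.0%) were bound against 52.6% (permutation test, adjusted p = 0.043, close to the threshold). The receptor gene wit had a peak of signal 1278 in an intron, and the ligand gene dpp a peak of signal 1027 in an intron on 2L from 2433464 to 2433838. The peaks counted for the ligand gene gbb (1700) and for Med (1477) lay at neighbouring genes, in a non-coding exon inside ytr and 21 bp upstream of Mnat9. Counting only summits within 500 bp of a gene's own TSSs, 48.0% of EGF receptor pathway genes (permutation test, adjusted p = 0.43) and 45.0% of BMP pathway genes (adjusted p = 0.50) were bound, neither past the test. Random placements of the peaks, which keep each gene's own span, bound more of these genes than random lists did. They gave 65.1% for EGF receptor pathway genes (permutation test, adjusted p = 0.038) and 43.15% for Notch pathway genes (adjusted p = 0.0095). For BMP pathway genes they gave 61.6%, and these did not pass (permutation test, adjusted p = 0.16). Within genes alone, 37.5% of Notch pathway genes were bound against 21.0% in random lists, which did not pass (permutation test, adjusted p = 0.075).

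Genes that respond to the moulting hormone ecdysone, whose pulse opens the prepupal stage, were also bound more often. The count was 21 of 25 (84.0%, random lists 55.1%, permutation test, adjusted p = 0.0084). The nuclear receptor gene Hr4 had 14 summits, the strongest of signal 1538 in an intron on X from 1951711 to 1952099, with a mean rank of 75.3 ± 36.3 (SD, n = 3). E23, which encodes an ABC transporter, had 8, the strongest of signal 1277 lying 209 bp upstream of its TSS. Eip78C (972) and ImpL2 (1063) had theirs in introns, where the nearest TSSs were those of CG43218 and CG46460. By the same permutation test, this call was lost with peaks matched in both libraries other than replicate 4 (72.0%, adjusted p = 0.060), with the 3785 strongest peaks (64.0%, adjusted p = 0.073), with summits near the TSS (44.0%, adjusted p = 0.50) and with random placements of the peaks (adjusted p = 0.13).

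Ribosomal protein genes stood farthest above their random lists in percentage points, and cuticle protein genes stood below theirs. Of 88 ribosomal protein genes, 65 (73.9%) were bound against 24.8% (permutation test, adjusted p = 0.0038), and 58 had a summit within 500 bp of a TSS of their own (65.9% against 11.7%, adjusted p = 0.0019). Strong peaks counted for this list lay at neighbouring genes: that for RpS19b (1289) in an intron of CG5854, that for RpL31 (1286) in an intron of clos and that for RpL3 (917) in the 3′ UTR of scpr-C, 105 bp upstream of CG17726. Of 118 cuticle protein genes, 13 (11%) were bound against 24.0% (permutation test, adjusted p = 0.0047), and 0 had a summit within 500 bp of a TSS. The strongest peak counted, for Cpr31A (1062), lay in an intron of its neighbour Pen, and a peak of signal 530 in intergenic sequence was shared by Cpr72Ea, Cpr72Eb and Cpr72Ec. Within genes alone, 2.54% of cuticle protein genes were bound against 4.82% in random lists, which did not pass (permutation test, adjusted p = 0.49).

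The wing vein list, which holds net and rho, did not pass: 21 of 28 genes (75.0%) were bound against 58.4% (permutation test, adjusted p = 0.17). Its strongest peaks were those counted for gbb, dpp and Egfr and a peak in an intron of px (905), 225 bp upstream of a TSS. With the 3785 strongest peaks, 71.4% of its members were bound against 44.3%, which passed (permutation test, adjusted p = 0.014). Of 25 bHLH genes, 11 were bound (44.0%, permutation test, adjusted p = 0.59), with Myc (939), crp (812) and Mnt (809) holding intronic peaks above that of net. Hox and axis selector genes (8 of 18, permutation test, adjusted p = 0.29), heat shock genes (8 of 17, adjusted p = 0.29) and tRNA genes (83 of 290, adjusted p = 0.088) did not pass. Antp (355), wg (348) and hth (289) had intronic peaks, and Dll (307) had a peak 117 bp upstream of its TSS. Hsp83 had a peak of signal 1108 in its intron and Hsp26 a peak of signal 890 lying 151 bp upstream, while Hsp23 was counted by the peak at Hsp27. The strongest tRNA peak (1291) lay 190 bp upstream of tRNA:Tyr-GTA-1-8 and counted also for tRNA:Tyr-GTA-1-6 and tRNA:Tyr-GTA-1-7, and that for tRNA:Val-CAC-2-3 (834) lay upstream of CG1142. Among peaks matched in both remaining libraries, the share of heat shock genes was 29.4% without replicate 3 (random lists 22.3%) or without replicate 4 (random lists 23.8%). That of tRNA genes was 18.6% without replicate 1 (random lists 16.4%) and 19.0% without replicate 4 (random lists 18.1%). Over all peaks, random lists had 29.6% for heat shock and 23.6% for tRNA genes. Within 5 kb, 51% of tRNA genes were bound against 40.8% in random lists (permutation test, adjusted p = 0.0025). This p takes tRNA genes as independent, although neighbours shared peaks. Random placements of the peaks keep the genes in place and were run at 2 kb only. By these, tRNA genes did not pass (28.6%, random 20.6%, permutation test, adjusted p = 0.12).

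None of the 8 cell type marker lists passed the test in the whole-animal chromatin. Bound members were 10 of 20 for muscle, 7 of 18 for neuron, 6 of 10 for glia, 5 of 12 for fat body, 3 of 12 for hemocyte, 2 of 14 for salivary gland, 8 of 9 for trachea and 2 of 10 for germline. Among peaks matched in both remaining libraries, the tracheal share fell from 88.9% to 55.6% without replicate 4, and 0 germline genes were bound without replicate 1 or without replicate 3. Over all peaks, the adjusted permutation p of the 8 lists ranged from 0.17 for neuron and hemocyte to 1.00 for muscle and fat body. Neuronal genes were bound less often with the 3785 strongest peaks (16.7% against 46.1%, permutation test, adjusted p = 0.041). Over all peaks they were also below random placements of the peaks (38.9% against 76.6%, permutation test, adjusted p = 0.0095). Random lists gave 61.5% there, and scattered placements can bind more genes than clustered peaks, so this p may be too small. Of muscle genes, kirre (746) had an intronic peak, Zasp52 (582) and sls (555) peaks in adjoining intergenic sequence, and the peak counted for Mef2 (1661) lay near the TSS of Pdrg1. Of neuronal genes, Rbp9 (456) and ChAT (192) had intronic peaks, while those counted for elav (1166) and Syx1A (315) lay in introns of arg and eIF4EHP. Of glial genes, loco (518) and Gs2 (240) had intronic peaks, moody (822) a peak 190 bp upstream of its TSS, and that counted for gcm2 (243) lay in the 5′ UTR of Trx2. Of fat body genes, Lsd-2 (865) had a peak in its 3′ UTR, bmm (452) an intronic peak and Lsd-1 (282) a peak at its TSS, while that counted for Lsp2 (339) lay near the TSS of DEF8. The peak counted for the hemocyte gene ush is that nearest to cbt, srp (318) had a peak 1431 bp upstream and that counted for Pxn (202) lay near CG42245. The salivary gland genes CrebA (388) and fkh (292) had peaks within 500 bp upstream. Of tracheal genes, apt (410) had an intronic peak, bnl (305) and Gasp (292) peaks upstream of their TSSs and that counted for serp (287) lay in intergenic sequence next to it. The germline gene bgcn (345) had a peak in its 5′ UTR, and that counted for nanos (155) lay in the 5′ UTR of CG11779. CrebA, Gasp and bgcn were matched in 2 of the 3 libraries.

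The highest signal counted for a named gene from the lists depended on the distance allowed. Within the gene alone it was 203 for Med, 673 for E23, 553 for RpL31, 374 for RpL3, 187 for Hsp23, 393 for Mef2, 233 for Zasp52, 287 for elav, 154 for Lsd-1 and 172 for bnl. Within 5 kb it was 1364 for Syx1A, 709 for Lsp2, 1700 for bgcn, where the peak is that counted for gbb, and 372 for nanos. These limits were added after seeing the data, and genes without a summit of their own have no value within the gene.

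**Figure D5:**
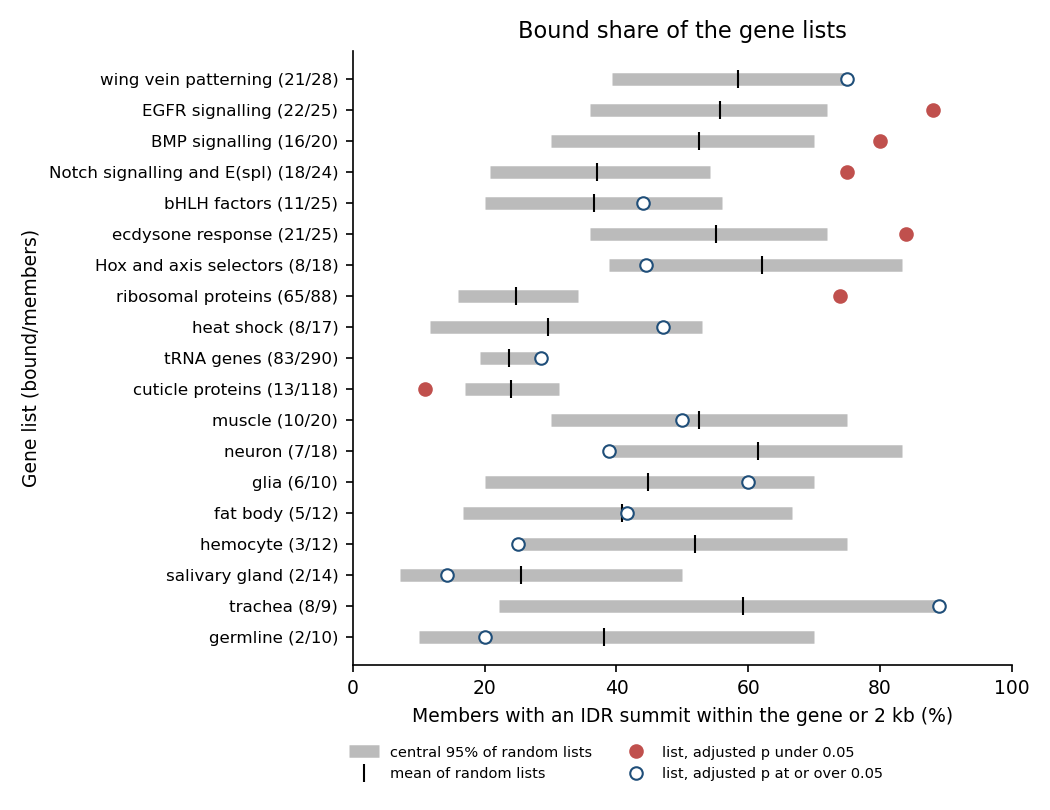
Bound share (x axis, %) of each of 19 lists (y axis, with bound and total members). Circles are the lists, filled where the adjusted p is under 0.05, grey bars the central 95% of 10000 random lists matched on gene span and ticks their mean; ribosomal protein genes stand at 73.9% against 24.8%, and cuticle protein genes at 11% against 24.0%.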

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

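Added after seeing the data were GC-matched windows, merged peaks, exact list distributions, relaxed peaks as chance for recovery, flanks without neighbours within 400 bp, other gene limits for the highest signal at named genes, and leaving out a library for peak number, arms, 6-mers, strong against weak peaks and ranks of single peaks. The promoter share of summits, the lower E-box share against flanks or relaxed peaks and the higher promoter share of strong peaks kept their direction and their side of the threshold under every alternative run except the GC-matched windows. Over the lists and their alternatives, 177 of the pairs kept their side of the threshold, 9 lost it and 4 gained it. The highest signal at named genes changed for 12 and stayed for 30 within the gene alone, and changed for 6 and stayed for 63 within 5 kb. The cause of the changes below was not tested, except where smaller peak sets or wider match rules change a count by construction.

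Requiring a match in all 3 libraries left 4297 peaks, and 4914 to 5045 with a library left out. Recovery was 69.4% with summits within 50 bp, 72.8% with mutual overlap and 86.5% with any overlap of intervals, 93.0% in library lists of double length and 95.9% for the 3785 strongest peaks. Mean Spearman's rho was 0.787 within the top lists, and the pairs left without a library gave 0.723 to 0.749. With expectations from relaxed peaks the arm ratios became 0.953 for 2L, 1.05 for 2R, 0.987 for 3L, 1.01 for 3R, 0.817 for chromosome 4 and 1.02 for X, none past the threshold. For the strongest 3785 peaks X had a ratio of 1.06 (exact binomial test, adjusted p = 0.11). Leaving out a library gave 1.05 to 1.08 for 2L, which passed without replicate 4, and 0.932 to 0.964 for 2R, which passed without replicate 1. Against GC-matched windows the E-box ratio was 1.05, and the 6-mer counts were 298 higher and 363 lower. With summits within 500 bp of a TSS, 3 lists passed instead of 6. BMP pathway genes lay close to the threshold (adjusted p = 0.045 by the exact distribution), and another draw of random lists during the analysis put them at it. The dm3 lists gave 7652 peaks and, for the arms, no changed call, with dm6 lengths; location, sequence and gene lists were not run on dm3. Depth is unknown and was not weighed; of the 1892 weakest peaks, 5.23% were matched in all libraries.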

Other observations

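The tests of words and E-boxes against GC-matched windows, between sets of peaks and without neighbouring summits, the rearranged patterns and the count of summits per gene were chosen after the result was seen, while those of words and E-boxes against the flanks were not, and of the tests on ribosomal protein genes, that on shared promoters was added when the others had been seen, but before its own result. Against random windows of the same GC count, the 10 6-mers highest at summits included GA repeats, words with GAGCG such as AGAGCG (ratio 2.23), CG repeats, ACAGTG and CAGTGC. Against the flanks the direction turned for 7 of these 10, CGCGCG, GCGCGC, AGAGCG, GAGCGA, GAGAGC, CGAGCG and AGAGAG, which were lower at summits (ratios 0.671 to 0.881, Fisher's exact test, highest adjusted p = 0.016). ACAGTG was at 7.36% of summits and 3.30% of matched windows (ratio 2.23, Fisher's exact test, adjusted p = 1.2e-48), and it was also above the flanks (ratio 1.57, adjusted p = 4.2e-15). CAGTGC had a ratio of 2.0 to matched windows and 1.34 to flanks. GAGAGA had a ratio of 2.13 to matched windows (Fisher's exact test, adjusted p = 9.5e-39) and 0.961 to the flanks, which were richer in GC (adjusted p = 0.51). GAGA repeats are bound by the GAGA factor, the product of Trl, at many fly promoters. GAGAGA was at 8.67% of the 1892 weakest summits and 4.44% of the 1892 strongest (Fisher's exact test, adjusted p = 8.5e-07 over 10 tests), and at 7.95% of promoter and 5.64% of other summits (adjusted p = 0.00025). AGAGAG was likewise at 8.83% of the weakest and 5.02% of the strongest summits (Fisher's exact test, adjusted p = 1.6e-05), and at 9.22% of promoter and 5.62% of other summits (adjusted p = 6.4e-08). CAGTGC was at 7.66% of the weakest and 5.66% of the strongest (Fisher's exact test, adjusted p = 0.022), without a called difference by promoter (adjusted p = 0.12), and ACAGTG passed neither test (adjusted p = 0.079 and 0.62). CAGCTG was at 4.86% of the weakest and 2.80% of the strongest summits (Fisher's exact test, adjusted p = 0.0020), and at 5.64% of promoter and 3.73% of other summits (adjusted p = 0.00025). These comparisons were not matched on GC content, which was 38.9% at the weakest and 33.4% at the strongest summits. Among E-box cores, CAGCTG was highest over GC-matched windows, at 4.42% of summits and 2.92% of windows (ratio 1.52, Fisher's exact test, adjusted p = 6.5e-10), without exceeding the flanks, and CATATG was above both backgrounds (ratios 1.27 and 1.26). CAAATG (ratio 0.883, Fisher's exact test, adjusted p = 0.0044) and CACCTG (ratio 0.835, adjusted p = 0.042) were below matched windows. CAAGTG (ratio 1.13, Fisher's exact test, adjusted p = 0.042) and CACATG (ratio 1.15, adjusted p = 0.042) were above them, although both were below the flanks. The GC-matched windows were not matched on location. IDR summits lay more at promoters (36.5%, random placements 13.4%) and less in exons (2.77%, random placements 19.7%). Differences of words and cores from these windows are therefore not separated from differences of location.

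The protein-coding genes with the most IDR summits within the gene or 2 kb were mostly long. The gene sbb had 30 summits over 79.1 kb, kirre 29 over 394 kb, Snoo 24, shn 23 over 58.3 kb, Tet 22 and the ecdysone-induced Eip75B 21 over 114 kb. For its length tara was densest among the 10 genes with most summits, with 19 summits over 34.7 kb. The X chromosome took 17.7% (95% interval 16.8 to 18.6) of the top list of replicate 1, 18.0% (17.1 to 18.9) of replicate 3 and 19.1% (18.2 to 20) of replicate 4.

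E-boxes were fewer at IDR summits than in their flanks. Overlap of flanks with neighbouring peaks does not account for it, since the difference stayed when peaks with another summit within 400 bp were left out (6192 peaks, exact McNemar p = 3.0e-11). Base composition is a candidate explanation: against windows of the same GC count the ratio was 1.05 (95% interval 1.01 to 1.08), and of 7 patterns of the same bases in another order, ACNNGT (1.06) and AGNNCT (1.05) were as high, while the others had 0.922 to 1.04. Against the flanks, however, these 7 had ratios from 0.892 to 1.15 and CANNTG the lowest of all, which the number of each base alone does not explain, so it stays open. For all E-boxes together, a summit excess specific to a bHLH protein is therefore not shown in either direction. The single core CATATG was above both backgrounds (ratios 1.26 to flanks and 1.27 to matched windows), and whether net binds it was not tested. Binding of net through other sequences or partners was not tested either.

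Ribosomal protein genes were bound more often than genes of like span. Peaks of neighbours within 2 kb do not account for it, since the share with a summit within 500 bp of their own TSSs was also higher (permutation test, adjusted p = 0.0019), nor do weak peaks near the IDR threshold, since with the 3785 strongest peaks 56 of 88 were bound (63.6% against 16.9%, permutation test, adjusted p = 0.0019). Shared promoters do not either: of 33 with no other protein-coding TSS within 1 kb, 19 had such a summit (57.6% against 6.87%, permutation p = 0.00020, the smallest 10000 lists can give). Signal that any GFP precipitation may give at active promoters stays open: relaxed peaks lay at 9 of the 30 ribosomal protein genes without an IDR summit near a TSS (30.0% against 10.6%, permutation p = 0.0054), as that explanation predicts, but weak binding of net would give the same, and this reading was settled after the value was seen. A precipitation from flies with GFP alone, not analysed here, would be needed to tell them apart, and no biological explanation was tested.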
